A study of Homo sapiens with 12 samples.

How the data were processed

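RNA was measured by sequencing in K562 cells, an established human chronic myeloid leukaemia cell line that can take on megakaryocyte or erythroid features in culture. Per the labels, polyT-selected RNA was fragmented and copied into cDNA, and the libraries were amplified by PCR. The 12 libraries form 4 groups of 3: negative control siRNA (siNC) or siRNA against RHOB (siRHOB), each in growth medium or in megakaryocyte differentiation medium (MK medium) for 3 days. The composition of the MK medium is not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

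The authors deposited a table of whole-number read counts per gene symbol and a table of FPKM values, each with 1 column per library, and every column was matched to its sample by its name. The submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.2, edgeR and the build GRCh37.p13, with no role or order. Settings for strand, for reads that map to several genes and for the annotation are not given in the sources used here. The deposited FPKM values equal the counts divided by a fixed gene length and by the total of the library's column. Genes with near-identical copies (HBG1 and HBG2, HBA1 and HBA2, CCL3 and CCL3L1, the replication-dependent histones) are therefore uncertain, as are genes that overlap on opposite strands. No coordinates are given, because no annotation of GRCh37 was used here. Library totals lay between 34412558 and 54048161 reads, and the 10 most abundant genes of a library took 3.88% to 4.62% of its reads. Intervals and floors given for low counts cover counting error only, since PCR copies are not independent molecules.

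The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. It was two-sided, with robust dispersion, TMM scaling, filterByExpr by group and a Benjamini-Hochberg adjusted p under 0.05. All 12 libraries entered a single fit of 4 group means with no further covariate, so that the groups shared an estimate of the spread. The filter kept 14026 of 19225 genes. The 5 contrasts were siRHOB against siNC in each medium, MK medium against growth medium for each siRNA, and the difference of the siRNA effects between media. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values are TMM-normalised, and logarithms of CPM used a prior count of 2. Where a group had 0 reads of a gene over its 3 libraries, the fold is a lower bound against 3 reads over the group. Where it had few reads, the ratio has an exact 95% counting interval.

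Gene lists were tested with camera on the same fit, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast. The tests were run again with an estimated correlation. A list needed at least 3 tested members, which 24 of 25 lists had. Mitochondrially encoded genes were not analysed here. A few genes and a pair of lists are not reported here, though the lists count among those tested. The other lists were megakaryocyte and platelet, globin, haem synthesis and iron uptake, erythroid membrane and regulator, haematopoietic transcription factor, G1/S and DNA replication, G2/M and mitosis, cyclin and cyclin-dependent kinase regulator, microtubule, SRF and MRTF target, immediate early and MAP kinase feedback, integrin and extracellular matrix, cytokine, chemokine and NF-kB, interferon response, integrated stress and unfolded protein response, cholesterol synthesis, apoptosis regulator, monocyte and granulocyte, lymphoid, fibroblast, epithelial and endothelial, histone, and ribosomal protein genes.

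The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule took RHOB, RHOA and RHOC. It took the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, which chance gives for 10% of genes with 3 against 3 libraries. It took up to 4 members of each list with the smallest adjusted p, or the most abundant members where few passed. It also took a fixed set of lineage, cell cycle and cytoskeleton genes. RHOB was also compared by exact permutation of CPM on the log2 scale.

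Replicates were compared before use. Within groups, log CPM correlated at 0.991 to 0.993 between replicates 1 and 2 and at 0.958 to 0.983 between replicate 3 and either. The chi-square per gene, over genes with at least 20 reads in a pair, was 4.21 or more, above sampling noise, so no library was counted as a copy. The shared replicate numbers were checked for pairing through the correlation between groups of deviations from the group mean. It was 0.151 to 0.601 for number 1, 0.190 to 0.476 for number 2 and 0.340 to 0.834 for number 3, each above the minimum of 0.1 set beforehand, so the numbers pair the samples by that rule. Replicates 1 and 2 taken crosswise gave 0.149 to 0.564, and replicate 3 with 1 or 2 gave -0.716 to -0.194, so the pairing rests on the separation of replicate 3. The correlations and the counts of calls with and without a block on the replicate number came out of the same first run. The unblocked design had been fixed earlier and stayed the main result.

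Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone, the replicate block, a minimum fold of 1.5 (glmTreat), limma on log2(FPKM + 1) and log2(FPKM + 0.1) with genes at an FPKM of at least 1 in 3 libraries, the former also without that filter, and each library left out in turn. Replicates 1 and 2 alone were added after the data were examined, as was camera with both an estimated correlation and the block. The fits were tested on simulated counts, drawn independently around each gene's mean over all 12 libraries, with no difference shared by the replicate 3 libraries. For siRHOB against siNC in growth medium (13828 genes), edgeR recovered 25.4% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 6 false calls. In MK medium (13808 genes) the shares were 22.4%, 62.7% and 87.9%. Figures were drawn with matplotlib 3.10.9.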

Results

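The experiment addressed the part that RHOB, a small GTPase that acts on the actin cytoskeleton, plays in megakaryocyte and erythroid differentiation. K562 cells received control siRNA or RHOB siRNA and were kept in growth medium or MK medium, with 3 libraries per group. Totals ranged from 38653567 to 54048161 reads per library in growth medium and from 34412558 to 41872422 in MK medium. Within each group, replicate 3 lay apart from replicates 1 and 2. The SD across genes of the log2 difference was 0.67, 0.65, 0.83 and 0.70 for replicate 3 against the mean of the others, in growth medium with siNC and siRHOB and MK medium with siNC and siRHOB, and 0.43, 0.47, 0.39 and 0.38 between replicates 1 and 2.

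RHOB, the siRNA target, was examined first in every library. In growth medium its level was 4.10 ± 2.44 CPM with siNC and 2.31 ± 1.60 CPM in the libraries labelled siRHOB (SD, n = 3). The siRHOB library held 51.1%, 70.5% and 32.7% of the RHOB level of the siNC library in pairs 1, 2 and 3, lower in 3 of 3 pairs. The log2 fold change was -0.83 ± 0.72 (SE, adjusted p = 1, edgeR), which did not exceed the replicate spread. In MK medium RHOB stood at 18.6 ± 12.3 CPM with siNC and 16.7 ± 4.90 CPM in the libraries labelled siRHOB (SD, n = 3). The siRHOB libraries held 97.9%, 153% and 67.7% of their siNC partners, lower in 2 of 3 pairs, and the log2 fold change was -0.15 ± 0.69 (SE, adjusted p = 1). Exact two-sided permutation of the 3 against 3 libraries gave p = 0.5 in growth medium and p = 1 in MK medium, where the smallest possible is 0.1. Exact sign flips of the pairs gave p = 0.25 and p = 1, with 0.25 the smallest possible. Within pairs the mean log2 ratio was -1.03 ± 0.56 in growth medium, larger than the spread between pairs, and 0.01 ± 0.59 in MK medium, smaller than it (SD, 3 pairs). No test passed in either medium, though the exact tests could not do so at this size, and the groups are called by their labels throughout. The related and more abundant RHOA differed by 0.02 ± 0.07 and RHOC by -0.03 ± 0.11 on the log2 scale in growth medium (SE), and by -0.05 ± 0.07 and 0.04 ± 0.11 in MK medium.

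**Figure D1:**
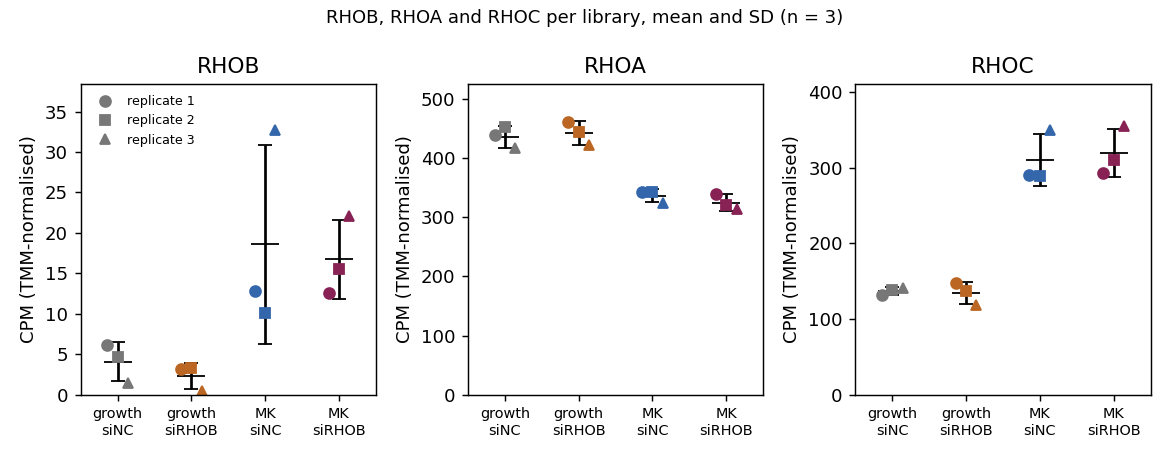
TMM-normalised CPM (linear axes from 0) of RHOB, RHOA and RHOC in the 12 libraries, by group, with symbols for replicate numbers, a horizontal line for the mean and bars for the SD (n = 3). RHOB in the libraries labelled siRHOB averaged 2.31 CPM against 4.10 CPM in growth medium and 16.7 against 18.6 CPM in MK medium.

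The effect of MK medium was compared first in cells with control siRNA. Megakaryocyte and platelet genes rose: of 29 tested, 26 rose and 1 fell, and 27 rose and 2 fell when adjusted over the list alone. ITGB3 and ITGA2B, which encode the subunits of the platelet fibrinogen receptor, rose by 7.59 ± 0.85 and 4.17 ± 0.27 on the log2 scale (SE, n = 3 against 3, adjusted p = 4.07e-05 and 6.77e-07). ITGA2B went from 12.7 ± 1.48 to 229.9 ± 67.0 CPM and ITGB3 from 4.17 ± 4.10 to 805 ± 336 CPM (SD, n = 3). Without Ctl_siNC 3 the log2 rise of ITGB3 was 8.77. PLEK, the platelet protein pleckstrin, rose by 6.32 ± 0.44, P2RX1, an ATP receptor of platelets, by 3.40 ± 0.21, PDGFA by 3.91 ± 0.31, and TUBB1, the tubulin of the platelet marginal band, by 1.97 ± 0.35. VWF had 0 reads in growth medium and 182 in MK medium, at least 75.4-fold higher against a floor of 3 reads over the group (46.6-fold without Ctl_siNC 2). Medians of these genes in replicate 3 lay 0.54 and 0.43 above replicates 1 and 2 on the log2 scale in growth and MK medium. The list passed camera at the preset correlation (adjusted p = 3.79e-07), but not with an estimated correlation (adjusted p = 0.32 with an estimated correlation).

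Erythroid genes moved in both directions. Of 31 erythroid membrane and regulator genes, 12 fell and 6 rose, with the same counts when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0825). CA1, an erythrocyte carbonic anhydrase, changed by -4.22 ± 0.42 on the log2 scale (SE), GYPC by -1.60 ± 0.17 and KLF1, an erythroid transcription factor, by -1.27 ± 0.41 (adjusted p = 1.21e-05, 1.74e-05 and 0.0216, edgeR). Of 8 globin genes, 3 rose and none fell (2 rose when adjusted over the list alone, camera adjusted p = 0.464). The embryonic globin HBE1 rose by 1.38 ± 0.26, from 1429 to 3713 CPM (adjusted p = 0.000918). The paralogs HBG2 (0.88 ± 0.34, adjusted p = 0.0465) and HBA1 (0.92 ± 0.30, adjusted p = 0.0216) rose, but the HBG2 call was lost without any of Ctl_siNC 1, 2 or 3 or MK_siNC 1 or 2 (log2 fold changes 0.97, 0.78, 0.89, 0.66 and 0.75) and the HBA1 call without Ctl_siNC 1 or 3 or MK_siNC 1 or 2 (log2 fold changes 0.89, 0.84, 0.58 and 0.88). In MK medium the medians of replicate 3 lay -1.17, -0.77 and -0.57 from replicates 1 and 2 on the log2 scale for globin, erythroid membrane and regulator, and haem and iron genes, and in growth medium 0.07, 0.07 and -0.03. The medians of the change in MK medium were -0.42 and -0.19 for the latter 2 lists. Of 21 haem synthesis and iron uptake genes, 5 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.534). ALAS2, the first enzyme of erythroid haem synthesis, rose by 0.85 ± 0.22, and TFRC, the transferrin receptor, changed by -1.58 ± 0.23.

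Of 30 haematopoietic transcription factor genes, 13 rose and 8 fell (14 and 8 when adjusted over the list alone, camera adjusted p = 0.876). MYB and MYC changed by -1.72 ± 0.14 and -1.65 ± 0.13 on the log2 scale and IKZF1 by -1.65 ± 0.16 (SE, adjusted p = 3.48e-06, 2.91e-06 and 1.2e-05). GATA1 rose by 0.49 ± 0.14 (adjusted p = 0.0123), a call lost without Ctl_siNC 1 or MK_siNC 1 (log2 fold changes 0.45 and 0.39). GATA2 stood at 0.07 ± 0.33 (adjusted p = 0.871), but passed as lower with replicates 1 and 2 alone, a choice made after the data were examined. ERG had 0 reads in growth medium and 1242 in MK medium, at least 515-fold higher (318-fold without Ctl_siNC 2). FLI1 had 1 read in growth medium and 231 in MK medium, a ratio of 287 (95% interval 51.1 to 11396), made up of 2, 7 and 222 reads in replicates 1, 2 and 3. Its fitted log2 change of 7.61 passed, but not without MK_siNC 3 (3.61) or without Ctl_siNC 1, 2 or 3 (7.23, 7.09 and 9.35), nor by DESeq2 (8.04). The ratio was 17.1 without MK_siNC 3, 178 without Ctl_siNC 2 and at least 64.4 without Ctl_siNC 3.

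Cell cycle genes fell. Of 44 G1/S and DNA replication genes, 40 fell and none rose, and of 52 G2/M and mitosis genes 45 fell and none rose (40 and 46 when adjusted over the list alone). UHRF1 changed by -1.43 ± 0.09, AURKB, a mitotic kinase, by -1.28 ± 0.08, CCNB1, cyclin B1, by -0.80 ± 0.10 and CDK1 by -0.36 ± 0.09 on the log2 scale (SE, adjusted p = 6.44e-07, 6.71e-07, 3.99e-05 and 0.00442). Both lists passed camera (adjusted p = 1.29e-11 and 9.99e-09), and neither did with an estimated correlation (adjusted p = 0.627 with an estimated correlation for both). Medians of replicate 3 in MK medium lay -0.37 from replicates 1 and 2 for each list, and in growth medium 0.03 and -0.19, against list medians of -0.76 and -0.61 for the change in MK medium. Of 31 cyclin and cyclin-dependent kinase regulators, 10 rose and 16 fell (11 and 16 when adjusted over the list alone, camera adjusted p = 0.209). The rises included CDKN1A, the inhibitor p21 (3.61 ± 0.27, from 7.43 to 90.8 CPM), and CCND1, cyclin D1 (3.18 ± 0.30). The falls included CCND2, cyclin D2 (-1.74 ± 0.08), SKP2, part of the ubiquitin ligase that degrades CDKN1B (-1.91 ± 0.10), and CDKN1B itself (-0.92 ± 0.08).

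Cytoskeleton genes were mixed. RHOB rose by 2.18 ± 0.73 on the log2 scale (SE, adjusted p = 0.0248), a call lost without Ctl_siNC 2, Ctl_siNC 3 or MK_siNC 3 (log2 fold changes 2.28, 1.77 and 1.48). RHOC rose by 1.18 ± 0.11 and RHOA changed by -0.38 ± 0.07 (adjusted p = 6.58e-06 and 0.000608). MYH9, the heavy chain of non-muscle myosin IIA, rose by 1.98 ± 0.09, from 287 to 1134 CPM, while MYH10, that of myosin IIB, changed by -1.18 ± 0.20. VCL, vinculin, rose by 1.21 ± 0.07, TLN1, talin, by 1.15 ± 0.10, and ACTB stood at -0.17 ± 0.11 (adjusted p = 0.203). Of 36 microtubule genes, 11 rose and 13 fell, also when adjusted over the list alone (camera adjusted p = 0.763), among them TUBA1A (2.33 ± 0.14), TUBB3 (2.52 ± 0.16) and STMN1, a microtubule destabiliser (-1.29 ± 0.11). SRF and MRTF targets rose in 15 of 28 cases and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.00258, and adjusted p = 0.627 with an estimated correlation).

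**Figure D2:**
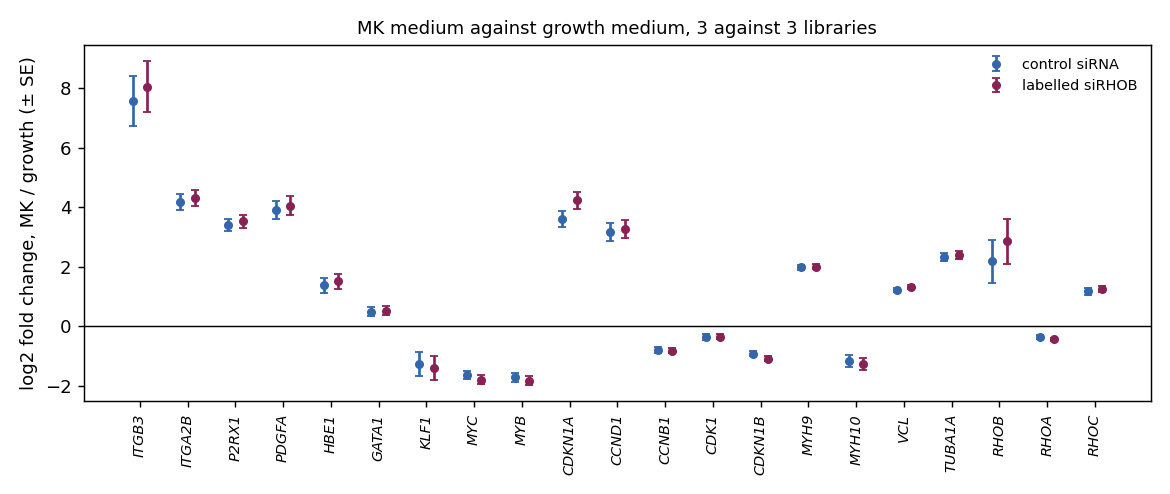
Log2 fold change of named genes in MK medium against growth medium for control siRNA (blue) and for the libraries labelled siRHOB (purple), with SE bars from the edgeR fit of 3 against 3 libraries. ITGB3 lies at 7.59 and 8.06 and MYB at -1.72 and -1.83.

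Further lists also had more members that rose than fell, and 4 of them are given here. Of 48 integrin and extracellular matrix genes, 31 rose and none fell (32 when adjusted over the list alone). ITGB5 rose by 3.37 ± 0.18 and COL6A3, a collagen VI chain, by 7.48 ± 0.73 on the log2 scale (SE, adjusted p = 1.8e-07 and 1.71e-05). Of 43 immediate early and MAP kinase feedback genes, 27 rose and 2 fell, also when adjusted over the list alone, with NR4A1 at 5.17 ± 0.54. Of 36 cytokine, chemokine and NF-kB genes, 24 rose and 2 fell (27 and 2 when adjusted over the list alone), with CCL2 at 9.87 ± 1.37. Of 32 interferon response genes, 13 rose and 2 fell (11 and 2 when adjusted over the list alone), with STAT2 at 1.09 ± 0.07. Without MK_siNC 3 the log2 rises of COL6A3, NR4A1 and CCL2 were 6.57, 4.47 and 8.13. CCL2 stood at 55.1, 64.7 and 479 CPM in MK_siNC 1, 2 and 3. These 4 lists passed camera (adjusted p = 6.2e-05, 0.00086, 0.00303 and 0.0499), each with adjusted p = 0.627 with an estimated correlation. The interferon call was lost without Ctl_siNC 1, Ctl_siNC 2 or MK_siNC 3 (adjusted p = 0.0719, 0.0731 and 0.105) and with RLE scaling (0.0559). Medians of replicate 3 in MK medium lay 1.10, 1.08, 1.14 and 0.45 above replicates 1 and 2 for these lists. In growth medium they lay 0.59, -0.62, 0.05 and 0.88 from them, against list medians of 2.12, 1.65, 1.67 and 0.94 for the change in MK medium. The largest changes outside them included GZMB, granzyme B, with 0 reads in growth medium and 11376 in MK medium, at least 4716-fold higher (2964-fold without MK_siNC 3, which held 6694 of the reads, and 2916-fold without Ctl_siNC 2). NMU, neuromedin U, changed by -3.79 ± 0.16.

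Of 53 cytosolic ribosomal protein genes, 41 fell and none rose (43 when adjusted over the list alone), with RPL14 at -0.84 ± 0.13 on the log2 scale (SE, camera adjusted p = 1.03e-05). Of 36 integrated stress and unfolded protein response genes, 13 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0259, and 0.0522 without MK_siNC 1), with the serine synthesis enzyme PSAT1 at -2.49 ± 0.19. Both lists had adjusted p = 0.627 with an estimated correlation. The median of replicate 3 for the stress list lay -0.24 from replicates 1 and 2 in growth medium and 0.33 in MK medium, against a list median of -0.33. For ribosomal protein genes it lay -0.13 and -0.18 from them, against -0.44, and for cholesterol synthesis genes -0.65 and -0.34, against -0.45. Of 26 cholesterol synthesis genes, 9 fell and 2 rose (8 and 2 when adjusted over the list alone, camera adjusted p = 0.194, 0.0107 with the replicate block, and 0.453 with the block and an estimated correlation). The enzymes LSS and SQLE went opposite ways (-1.61 ± 0.20 and 1.55 ± 0.24). Of 33 apoptosis regulators, 14 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.062), with the caspase-8 regulator CFLAR at 2.65 ± 0.08. Of 21 histone genes, 1 rose and 2 fell (0 and 1 when adjusted over the list alone, camera adjusted p = 0.484). How far polyT selection captured RNA of the histone genes was not examined, so these counts do not show its level in the cells. The histone median of replicate 3 lay below replicates 1 and 2 in both media, at -0.83 from them in MK medium and further in growth medium.

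Over all genes, 8256 of 14026 passed the threshold in MK medium with control siRNA, 4278 higher and 3978 lower. Of these, 2668 rose and 878 fell by more than 2-fold. Requiring more than a 1.5-fold change by glmTreat left 3686 genes.

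**Figure D3:**
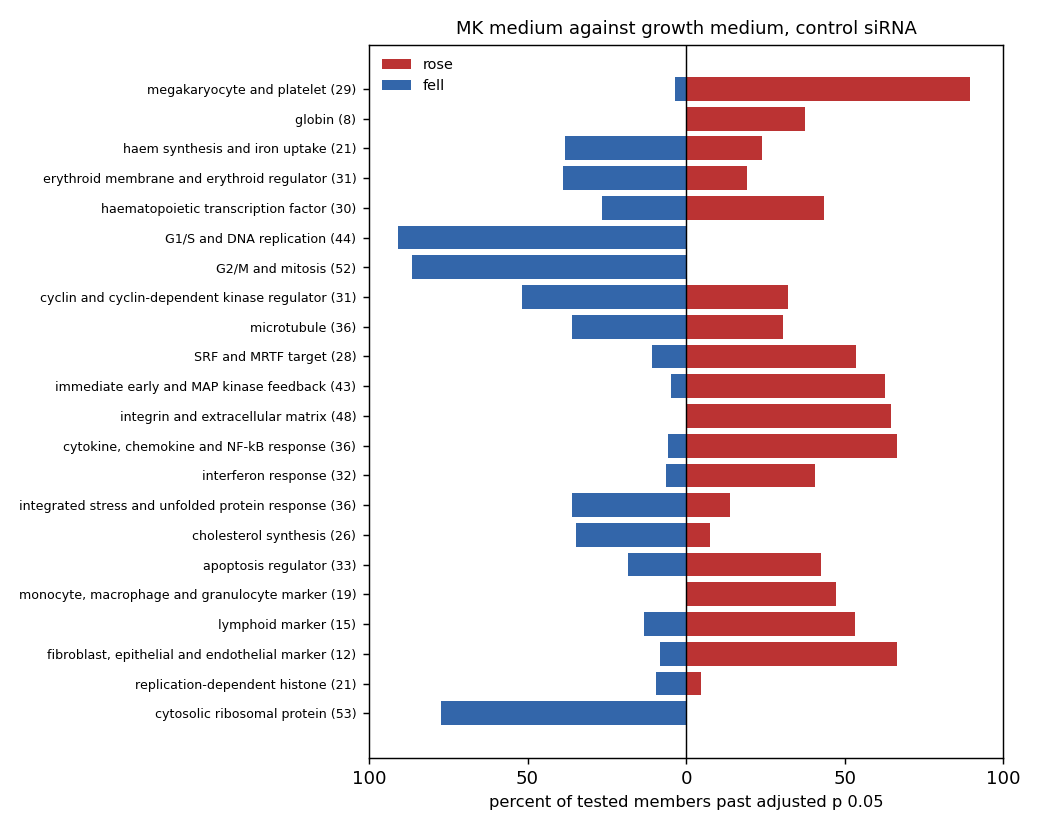
Share of the tested members of each list reported here (number in brackets) that passed adjusted p 0.05 in MK medium against growth medium with control siRNA, rising to the right and falling to the left of 0. Of 29 megakaryocyte and platelet genes 26 rose, and of 44 G1/S and DNA replication genes 40 fell.

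In the libraries labelled siRHOB, ITGB3 rose in MK medium by 8.06 ± 0.87 and ITGA2B by 4.30 ± 0.27 on the log2 scale, and KLF1 and MYB changed by -1.40 ± 0.41 and -1.83 ± 0.14 (SE, adjusted p = 2.89e-05, 4.93e-07, 0.0133 and 1.97e-06). Without Ctl_siRHOB 3 the rise of ITGB3 was 9.01. CDKN1A rose by 4.24 ± 0.28, CCND1 by 3.28 ± 0.30 and MYH9 by 2.01 ± 0.09, and RHOB by 2.86 ± 0.75 (adjusted p = 0.00772). Of the megakaryocyte and platelet list, 25 rose and 1 fell (27 and 1 when adjusted over the list alone). Of the G1/S and G2/M lists, 40 and 44 members fell (40 and 46 when adjusted over the list alone). Camera passed 9 lists, 6 higher and 3 lower. Adjusted p with an estimated correlation was 0.472 for megakaryocyte and platelet genes, 0.194 for fibroblast, epithelial and endothelial markers and 0.709 for the other 7. In all, 8436 genes passed, 4355 higher and 4081 lower, and glmTreat at 1.5-fold left 3914. Of the rises, 3933 were shared between the siRNA arms, against 1328 for independent lists, and of the falls 3764 against 1157. No gene passed in opposite directions. Log2 fold changes of the arms correlated across genes (r = 0.956, rho = 0.961). Genes are not independent replicates, and although the arms share no library, libraries of the same number deviate together.

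The siRNA arms were then compared within each medium, the comparison that addresses RHOB itself. No lineage, cell cycle or cytoskeleton gene passed. In growth medium ITGA2B differed by 0.06 ± 0.24, CCND1 by -0.16 ± 0.28, CDKN1A by -0.74 ± 0.27 and MYH9 by 0.08 ± 0.09 on the log2 scale (SE, adjusted p = 1 for each). In MK medium ITGA2B differed by 0.19 ± 0.23, CCND1 by -0.06 ± 0.27, CDKN1A by -0.11 ± 0.24 and MYH9 by 0.11 ± 0.09 (SE, adjusted p = 1 for each). By edgeR, 0 of 14026 genes passed in either medium. At an unadjusted p under 0.05 there were 156 genes in growth medium and 50 in MK medium, where 701 of 14026 are expected by chance. There were 301 and 115 with the replicate block, fitted in common to both media. Replicates 1 and 2 alone gave 812 and 338 of 13895. Of these counts only the 812 exceeded chance. Counts below chance mean that the p-values ran high, so 0 passing genes does not show that the siRNA had no effect. DESeq2 also called 0, with 183 and 54 at an unadjusted p under 0.05, and limma on the FPKM values called 0. With replicates 1 and 2 alone, chosen after the data were examined, 1 gene passed in growth medium: CXCL8, interleukin 8, at -1.70 ± 0.17 (SE, adjusted p = 0.00208). Its reads were 623, 633 and 95 with siNC and 167, 167 and 87 with siRHOB, and over all replicates it stood at -1.49 ± 0.96 (adjusted p = 1).

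In growth medium, 4 gene lists were lower in the libraries labelled siRHOB by camera at the preset correlation: integrated stress and unfolded protein response (adjusted p = 7.34e-05, median log2 -0.16), ribosomal protein (0.00321, -0.06), immediate early (0.013, -0.16) and cholesterol synthesis (0.0215, -0.10). None passed with an estimated correlation (adjusted p = 0.987 with an estimated correlation for each). No member of these lists passed singly, also when adjusted over the list alone. HSPA5, the chaperone BiP, stood at -0.16 ± 0.26 and SQLE at -0.09 ± 0.23. The list medians were below 0 in 3 of 3 pairs, except 2 of 3 for ribosomal protein genes. Each call was also lost with a single library left out. Such a removal also unbalances replicate 3 between the siRNA arms. With siNC, replicate 3 medians of these lists lay -0.24, -0.13, -0.62 and -0.65 from replicates 1 and 2. The losses therefore cannot tell a fragile call from this offset. Without Ctl_siNC 1 the adjusted p was 0.0581, 0.93, 0.978 and 0.895 in the order given, with the immediate early and cholesterol lists turned higher. Without Ctl_siNC 2 it was 0.325, 0.449 and 0.962 for the stress, immediate early and cholesterol lists. Without Ctl_siRHOB 3 it was 0.247, 0.865, 0.355 and 0.277, with all but the stress list turned higher. With the replicate block the immediate early list no longer passed (adjusted p = 0.0542) and G2/M genes did, higher (0.0103, and 0.893 with the block and an estimated correlation). In MK medium, ribosomal protein genes were lower in the libraries labelled siRHOB (adjusted p = 1.45e-12, median log2 -0.09, below 0 in 3 of 3 pairs, and adjusted p = 0.976 with an estimated correlation). That call was lost without MK_siRHOB 3 (adjusted p = 0.341), a removal that also unbalances replicate 3. With the block, cytokine genes were lower too (adjusted p = 0.0331), but not with the block and an estimated correlation (adjusted p = 0.912), and with replicates 1 and 2 alone the direction was higher (adjusted p = 0.573).

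The difference of the siRNA effects between media was tested as an interaction. No gene passed by edgeR, DESeq2 or limma, with 106 by edgeR and 124 by DESeq2 at an unadjusted p under 0.05. RHOB itself gave 0.68 ± 1.00 on the log2 scale (SE, adjusted p = 1). No list passed camera. With the block cholesterol synthesis genes did (adjusted p = 0.00251, higher), but not with the block and an estimated correlation (adjusted p = 0.987). Across genes, the siRNA log2 fold changes of the media had r = 0.0254 and rho = 0.0863, and r = 0.138 among 10175 genes with a mean of at least 5 CPM.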

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

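Replicates 1 and 2 alone and the estimated correlation with a block were chosen after the data were examined. Counts of genes in the MK comparisons stayed within 1.5 times of 8256 and 8436 under every alternative except glmTreat (3686 and 3914, by construction a stricter test). In the siRNA comparisons and the interaction, every alternative gave 0 genes except replicates 1 and 2 alone in growth medium, with 1. The replicate block fitted an effect of each number common to both media, and no fit paired the siRNA arms within a medium. Replicate 3 deviations correlated at 0.679 and 0.834 within a medium but only at 0.340 to 0.364 between media. The 0 genes therefore leave a paired comparison within each medium untested. The correlation of siRNA effects between media was 0.0254, and 0.102 from the compared groups alone, 0.138 on log2(FPKM + 1), 0.0724 on log2(FPKM + 0.1) and 0.113 without the FPKM filter. It ran from -0.0578 to 0.0531 with a library left out. The cause was not tested. The 25 list calls fell to 0 with an estimated correlation, with the block too, for each comparison, and became 45 with replicates 1 and 2 alone. The list count in growth medium (4) ran from 2 to 9 with a library left out (9 without Ctl_siNC 3). In MK medium (1) it ran from 5 to 16 (16 without MK_siNC 3), with 2 under the block and 10 with replicates 1 and 2. For the interaction (0) it ran from 0 to 13 (13 without MK_siNC 3), with 1 under the block and 9 with replicates 1 and 2. Leaving out a library unbalances replicate 3 between the siRNA arms. Splits with both replicate 3 libraries on the same side called 7 to 11 lists in growth medium and 15 to 17 in MK medium. How far such an imbalance accounts for these ranges was not tested. The replicate block gave 9330 and 9490 genes in the MK comparisons, which held 8242 of the 8256 and 8423 of the 8436. With control siRNA, GATA2 went from 0.07 to -0.34 on the log2 scale with replicates 1 and 2 alone, where it passed the threshold as lower. Of the other values of named genes in the MK comparisons under alternatives, 3793 kept their side of the threshold. Those called in both fits kept their direction, while the direction of values called in neither was not counted. Another 112 kept the direction and lost the call (39 of them under glmTreat), and 8 kept the direction and gained it. RLE scaling moved the median by at most 0.03 on the log2 scale. Filtered log2(FPKM + 1) values moved it by 0.06 with control siRNA and 0.07 with RHOB siRNA in the MK comparisons. Each of these scalings is relative to the rest of the library, so small fold changes are relative too.

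Depth did not limit the abundant genes. RHOB had 19 to 243 reads per library in growth medium and 357 to 1225 in MK medium, and its counting error was not separated from the spread between libraries. In libraries simulated independently around each gene's mean over all 12 libraries, most 2-fold changes were recovered (70.1% in growth medium and 62.7% in MK medium). Those means were not the levels of either medium, and replicate 3 was not set apart. The shares therefore do not give the sensitivity of the real siRNA comparisons.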

Other observations

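Markers of other cell types also moved in MK medium with control siRNA. Of 19 monocyte and granulocyte markers, 9 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0825, 0.0191 with the replicate block, and 0.220 with the block and an estimated correlation), with CD68, a lysosomal protein of macrophages, at 1.70 ± 0.17 on the log2 scale (SE). CSF1R had 3 reads in growth medium and 439 in MK medium, a ratio of 182 (95% interval 61.9 to 886). The ratio was 94.3 without MK_siNC 3, which held 290 of the reads, and at least 113 without Ctl_siNC 2, which held the 3 growth medium reads. Of 15 lymphoid markers, 8 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0602), with CD3D at 2.67 ± 0.20. Of 12 fibroblast, epithelial and endothelial markers, 8 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00296, and adjusted p = 0.202 with an estimated correlation). KRT8 and KRT18, a keratin pair, rose by 2.99 ± 0.15 and 2.98 ± 0.16, to 3945 and 2558 CPM, while EPCAM changed by -1.57 ± 0.14. Medians of replicate 3 lay 1.07, 0.46 and 0.02 above replicates 1 and 2 in growth medium and 0.75, 0.06 and 0.68 in MK medium for these 3 lists, against list medians of 1.10, 2.04 and 2.41 for the change. TERT, the catalytic subunit of telomerase, changed by -4.42 ± 0.49 (-5.12 without MK_siNC 2), and PKLR, the red cell pyruvate kinase, by -3.99 ± 0.71.

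Replicate 3 differed from replicates 1 and 2 in every group. The tests of depth and of a shared difference were chosen after the result was seen. Of 10175 genes with a mean of at least 5 CPM, 66 were over 2-fold higher in replicate 3 in all 4 groups and 10 over 2-fold lower. ITGAX, chosen after its values were seen, was higher by 2.81 to 3.77 on the log2 scale. Library depth is argued against, since the total of replicate 3 lay within the range of replicates 1 and 2 in 2 of the 4 groups, and so is a gene length trend, which took up at most 0.0071 of the variance. Deviations of replicate 3 correlated at 0.679 and 0.834 between the siRNA arms of growth and MK medium, and at 0.340 to 0.364 between media. Medians of immediate early genes lay at -0.62 and -0.49 in growth medium but 1.08 and 0.83 in MK medium (siNC and siRHOB). Those of histone genes were negative in all 4 groups. A difference shared by the replicate 3 cultures or libraries may account for part of it, and another part differed between media. Culture, passage and library batch stay open since the labels give none. No biological explanation was tested.

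In MK medium RHOB stood at 97.9%, 153% and 67.7% of the siNC partner in pairs 1, 2 and 3. Pair 1 was thus nearly equal. In growth medium RHOB was lower in 3 of 3 pairs, at 51.1%, 70.5% and 32.7%. Neither difference passed a test. The tests of an equal knockdown and of other labellings were chosen after the result was seen. If siRNA labels were exchanged in MK medium, the siRNA effects of both media should run opposite. Their correlation was 0.0254 over all genes, and among 10175 genes with a mean of at least 5 CPM it was 0.138, and 0.103 with the replicate block. Among the latter genes, 7 of 16 labellings exchanged within pairs gave a correlation of mean log CPM differences at least as large in size as the real one (0.120 real, 0.187 the highest other). An exchange therefore cannot be told apart from correct labels, since no effect stood out from the spread. A full exchange would only turn the sign of the mean log2 RHOB ratio within MK pairs, 0.01 ± 0.59 (SD, 3 pairs). By itself it would therefore not show RHOB lower in MK medium either. An equal proportional knockdown in both media could also be hidden by the spread, since the interaction of RHOB was 0.68 with an SE of 1.00, and this stays open. The 3 libraries per group keep both open, as well as a knockdown lost by day 3 of MK culture, which was not tested.

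Other splits of the same libraries bear on the counts. The sorting of splits by replicate 3 was chosen after their counts were seen. For each MK comparison, the real split gave 8256 and 8436 genes and the highest of the others 0, so 1 of the 10 splits gave as many. For the siRNA comparisons the real split and the others, 10 of 10, gave 0 genes. With 10 splits no share under 0.05 can be had. For the interaction, 40 of 40 drawn splits gave 0 genes, the real one included. A real count of 0 is met by every split, so these splits decide nothing for the siRNA comparisons or the interaction. Lists behaved otherwise. As many lists as the real split passed in 5 of 10 splits for siRHOB in growth medium (4 real, 11 the highest other), 8 of 10 in MK medium (1 and 17), 6 of 10 for MK medium with siNC (11 and 16) and 9 of 10 with siRHOB (9 and 15). Among splits that part all 3 pairs, as the real one does, the highest others were 1, 5, 11 and 15 lists. The other splits of the MK comparisons set 2 libraries of a medium against 1 and so carry part of the effect of the medium. That effect also widens the spread within each side of these splits. Neither their 0 genes nor the lists that pass in them therefore decide anything. For the siRNA comparisons, the 4 splits that put both replicate 3 libraries on the same side called 7 to 11 lists in growth medium and 15 to 17 in MK medium. The other 5, apart from the real one, called 0 to 1 and 0 to 5. The splits with the highest counts thus point to a structure of the libraries in which replicate 3 stands apart. In MK medium a pair of splits with replicate 3 on opposite sides called 5 lists, against 1 for the real split. The replicate 3 libraries deviated unequally there (SD 0.83 with siNC and 0.70 with siRHOB), so opposite sides need not cancel them. Those splits therefore do not decide whether replicate 3 accounts for all the calls.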
